A study of Neurospora crassa with 6 samples.

How the data were processed

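The series concerns ChIP-seq of histone H3 trimethylated at lysine 9 (H3K9me3) in mycelia of 6 strains of the filamentous fungus Neurospora crassa, with 1 library per strain. Per the labels' protocols, mycelia were grown for 16 h at 32 °C in minimal medium with 1.5% sucrose and fixed with 0.5% formaldehyde for 10 min. Chromatin was sheared for 15 min by sonication, about 10 ng of DNA entered each library, fragments of 225 to 425 bp were cut from a gel, and 9 PCR cycles followed. Bowtie2, a short-read aligner, is named in the submitters' processing notes. Its version, its settings and the read length were not given in the sources used here.

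The file analysed here is a genome sequence in FASTA format, as deposited by the authors, and it belongs to the series as a whole. It holds 20 sequences named as NC12 supercontigs per the file headers, and its only characters are the bases, N and lower-case bases. It carries no reads, counts, peaks or signal, so no ChIP value of any of the 6 strains was analysed here and sequencing depth is unknown. The comparisons of H3K9me3 between strains that had been planned before the data were examined were therefore not run, and no test between strains, error over replicates or p-value is given. What follows describes the sequence in which those comparisons are read. How the authors edited the sequence was not given in the sources used here.

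Gene names and positions came from a RefSeq gene table of the NC12 assembly, with 10590 genes. The 10397 genes on the 7 chromosomes were used, and 135 genes on unplaced sequence and 58 mitochondrial genes were left out. Whether these positions hold in the deposited sequence was checked with tRNA genes. The conserved T-loop motif was searched in each of 399 tRNA genes, on either strand, at every offset up to 2000 bp in each direction. On chromosomes II to VII and on chromosome I before his-3 the best offsets ran from -12 to 12 bp, centred on 0. After his-3 they ran from -588 to -564 bp, centred on -576. At these offsets 348 of 399 tRNA genes held the motif, and at offsets more than 100 bp away at most 8 genes of any chromosome did. Gene positions are printed as the NC12 gene table gives them. Distances use the deposited sequence, with genes after his-3 on chromosome I moved by -576 bp, which assumes that the change in length lies at the insert. Positions of the insert and of AT-rich regions are those of the deposited sequence and count from 1.

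AT-rich regions were called in non-overlapping windows of 1000 bp. A window was used if at least 50% of its bases were known, and was AT-rich if its GC content was below 40%. Adjacent AT-rich windows were joined. The TpA/ApT ratio (product index) and the (CpA+TpG)/(ApC+GpT) ratio (substrate index) are the usual measures of repeat-induced point mutation (RIP), the process by which Neurospora changes C to T in duplicated DNA before meiosis. Shuffled windows, 20 rounds per chromosome, kept the base counts of each window. LexA operator matches were sought as CTGT, 8 bases of any kind, then ACAG. Matches within 5 kb of his-3 counted as the target. The number outside it was set beside the 11 other palindromes made by reordering the half-site, and beside the number expected from a first-order Markov chain fitted separately to AT-rich and other sequence. Uniqueness was the share of k-mers of 36, 50 and 100 bases that occur once on both strands together. Vector elements and operators were found by exact match to textbook sequences.

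The 9 gene lists were fixed in advance, and 34 of their 39 members matched a symbol or synonym in the gene table. The named genes are his-3, the genes of the genotypes, the 5 annotated genes on each side of the insert and the matched list members; the longest AT-rich region of each chromosome and the region nearest to the insert on each side are also given. A rule to name genes near exact consensus operators applied to none, because there was no such match. A list's median distance was placed among 10000 random lists of protein-coding genes of the same size, as a description. Wilson 95% intervals on shares of windows or genes treat these as independent, and Poisson 95% intervals cover counting only. Scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. They were tested on simulated sequence, where all 250 planted AT-rich windows, all 40 planted operators and all 11804 planted repeated 50-mers were recovered. Alternatives covered the window size, the GC limit, a minimum region length, calling by the 2 RIP indices, and the operator pattern.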

Results

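The study asked what H3K9me3, a histone mark of silent chromatin, does when heterochromatin proteins are brought to a chosen site. All 6 strains carried operators of the bacterial repressor LexA (LexAO) beside his-3, a histidine biosynthesis gene. In 5 of them the DNA-binding domain of LexA was joined to a heterochromatin protein, which was DIM-5 (the H3K9 methyltransferase), HP1 (which binds H3K9me3) or HDA-1 (a histone deacetylase). HP1 was tethered in an otherwise intact strain, in a strain lacking hda-1 and in a strain lacking dim-2, which encodes the DNA methyltransferase. The strain with operators and no fusion was the control. Each strain had 1 H3K9me3 library, so each comparison (DIM-5, HP1 or HDA-1 against the control, and HP1 with against without hda-1 or dim-2) has 1 library on each side. ChIP signal was not analysed here. The values below describe the genome sequence made for the series, namely the target site, the AT-rich DNA that carries most H3K9me3 in this fungus, and the genes altered in the strains.

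The sequence comprised 20 supercontigs and 41036962 bases. The 7 longest, 12.1 to 12.7, matched chromosomes I to VII and held 40.5 Mb. Its GC content was 48.3%, and 391 gaps of unknown bases took up 40775 bases.

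The target lay on chromosome I, between his-3 and the next annotated gene, NCU03140, which is followed by lpl. A block of 196 bp at positions 4698233 to 4698428 of supercontig 12.1 held 180 lower-case bases, and no lower-case base occurred on any other supercontig. It contained 4 exact copies of the 31-bp sequence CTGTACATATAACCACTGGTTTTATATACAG, the reverse complement of the operator of the colicin E1 gene, in which a pair of LexA boxes overlap. The copies lay in 2 tandem sets. Within a set 5 bp separated them, and 13 bp lay between the sets. The array ran from 4698249 to 4698395, a span of 147 bp. Vector sequence flanked it on both sides, with a T7 promoter at 4698176 to 4698195 and a T3 promoter on the opposite strand at 4698494 to 4698513. The annotated end of his-3 (NCU03139, chromosome I, 4694770 to 4697885) was 347 bp before the block. NCU03140 began 1358 bp after it, and lpl (NCU03141) began 1.67 kb after it.

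**Figure D1:**
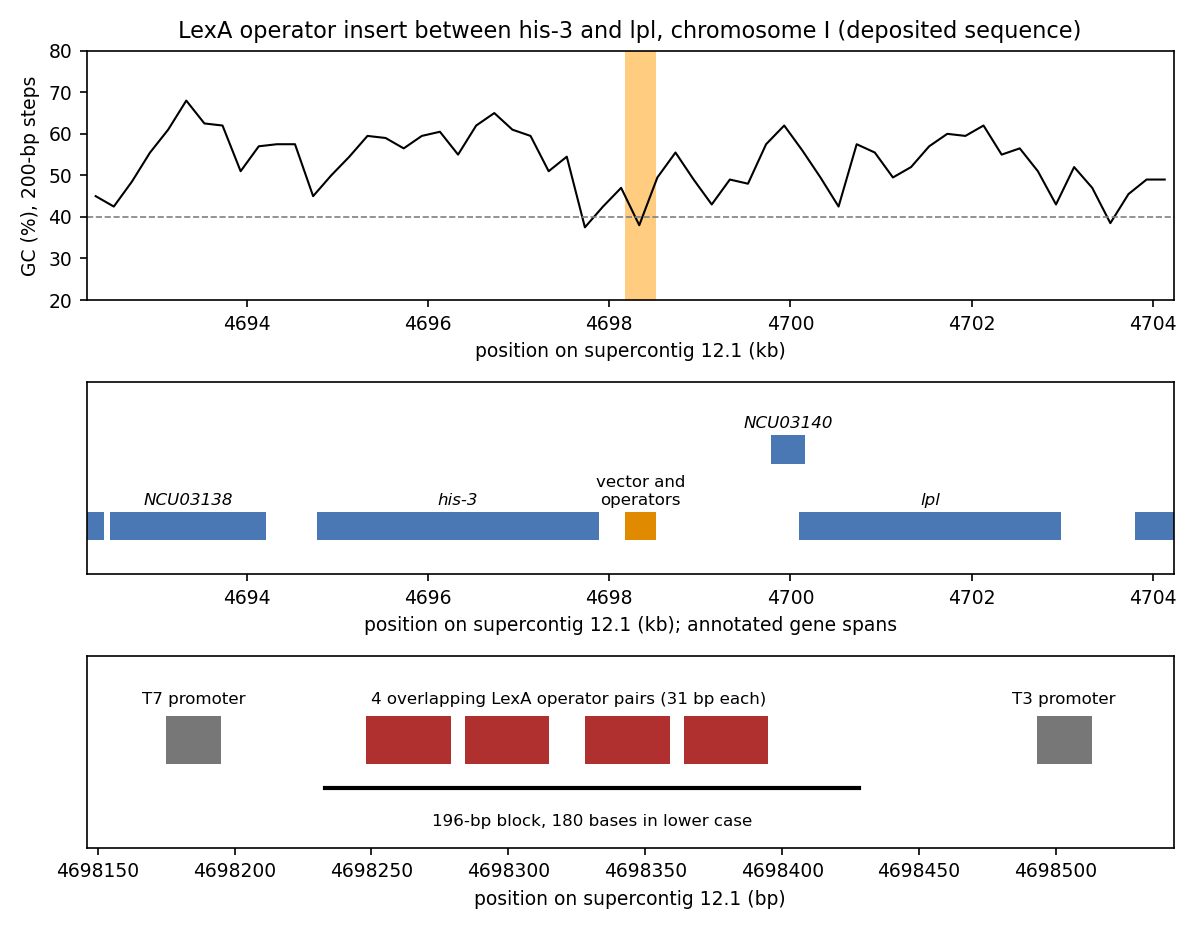
Target site on supercontig 12.1. Top, GC content (%) in steps of 200 bp with the 40% limit dashed and the stretch from T7 to T3 promoter shaded; middle, annotated genes (blue) and vector with operators (orange), with genes after the insert drawn at the shifted position; bottom, the 4 operator pairs (red) and both promoters (grey), from 4698176 to 4698513 bp. The insert sits 347 bp after his-3.

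The operators were placed outside AT-rich regions, in DNA with a GC content near that of other windows (median 52.2%). GC content was 55.9% over the 5 kb before the T7 promoter and 52.6% over the 5 kb after the T3 promoter. The 196-bp block itself had 38.3% GC, the operator array 35.4%, and the 1 kb centred on the block 46.5%. The 4 annotated genes before his-3 (NCU03135, NCU03136, NCU03137 and NCU03138) had GC contents of 53.7%, 54.1%, 53.5% and 56.9%. Those after the insert beyond lpl (NCU03142, NCU10470 and NCU03145) had 50.5%, 52.5% and 53.3%, while NCU03140 had 60.1% and lpl 53.8%. No base of any of these 10 neighbouring genes, his-3 included, lay in an AT-rich region.

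AT-rich DNA made up 16.5% of the sequence, or 6759 of 41035 windows of 1 kb (Wilson 95% interval 16.1% to 16.8%), in 390 regions. The interval treats windows as independent, although AT-rich windows lie in runs. Some settings moved the share beyond it, to 15.8% with regions of at least 5000 bp only and 17.1% with a GC limit of 42%. The region count also depended on the settings, with 911 for windows of 500 bp and 248 for regions of at least 5000 bp only. The windows fell into 2 classes, with a median GC of 27.8% in AT-rich windows and 52.2% in the others. Between the peaks of the distribution, at 26% and 52%, the sparsest bin of 1% width held 91 windows. Regions were mostly long: 248 of them reached 5 kb and these held 95.7% of AT-rich bases, while 66 consisted of 1 window. The share of AT-rich windows per chromosome ran from 13.7% on chromosome V to 19.3% on chromosome VII. The 12 supercontigs from 12.8 to 12.19 had 25.5% to 29.1% GC, and 564 of their 573 windows were AT-rich.

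**Figure D2:**
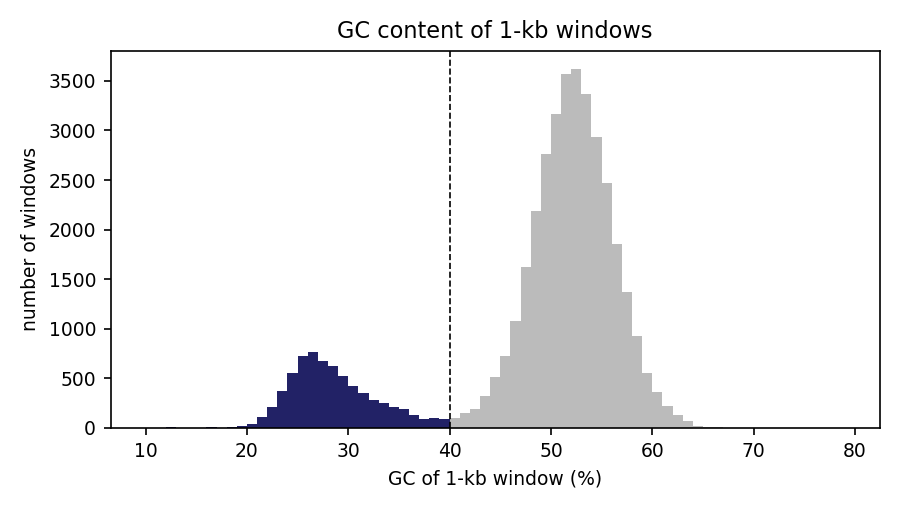
Number of 1-kb windows (y axis) by GC content in % (x axis), in bins of 1%; bars below the 40% limit are dark. The classes peak at 26% and 52%, and 91 windows fall in the sparsest bin between them.

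Each chromosome had an AT-rich region of at least 71.0 kb. The longest lay at 3741001 to 3972000 on chromosome I (231 kb, 30.1% GC). Chromosome VII followed with 197 kb at 2286001 to 2483000, and chromosome VI with 186 kb at 2771001 to 2957000. The longest unbroken regions were 126 kb on chromosome V (891001 to 1017000), 122 kb on chromosome III (842001 to 964000), 110 kb on chromosome II (3602001 to 3712000) and 71.0 kb on chromosome IV (894001 to 965000). Short interruptions split longer AT-rich stretches, as at 1155001 to 1366000 on chromosome II and 876001 to 1087000 on chromosome IV. No setting allowed for such interruptions when windows were joined. The longest regions of the chromosomes overlapped between 0 and 3 annotated protein-coding genes each. Over the chromosomes, 30 of 9729 protein-coding genes (0.308%, Wilson 95% interval 0.216% to 0.440%) and 5 of 399 tRNA genes (1.25%, 0.536% to 2.90%) lay at least 50% inside AT-rich regions. With windows called by indices of repeat-induced point mutation (RIP), 49 protein-coding genes did. The main call gives 4.84 protein-coding genes per Mb of AT-rich DNA against 283 per Mb elsewhere.

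AT-rich windows carried the dinucleotide pattern of RIP on all 7 chromosomes. Their median TpA/ApT index was 1.37 to 1.38 per chromosome (SD over windows 0.109 to 0.127), against 0.657 to 0.673 in the other windows. Their median substrate index, which falls as CpA and TpG are lost, was 0.314 to 0.338, against 1.19 or more. Windows of 1 chromosome are not independent replicates, and the 7 chromosomes all showed the same direction.

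**Figure D3:**
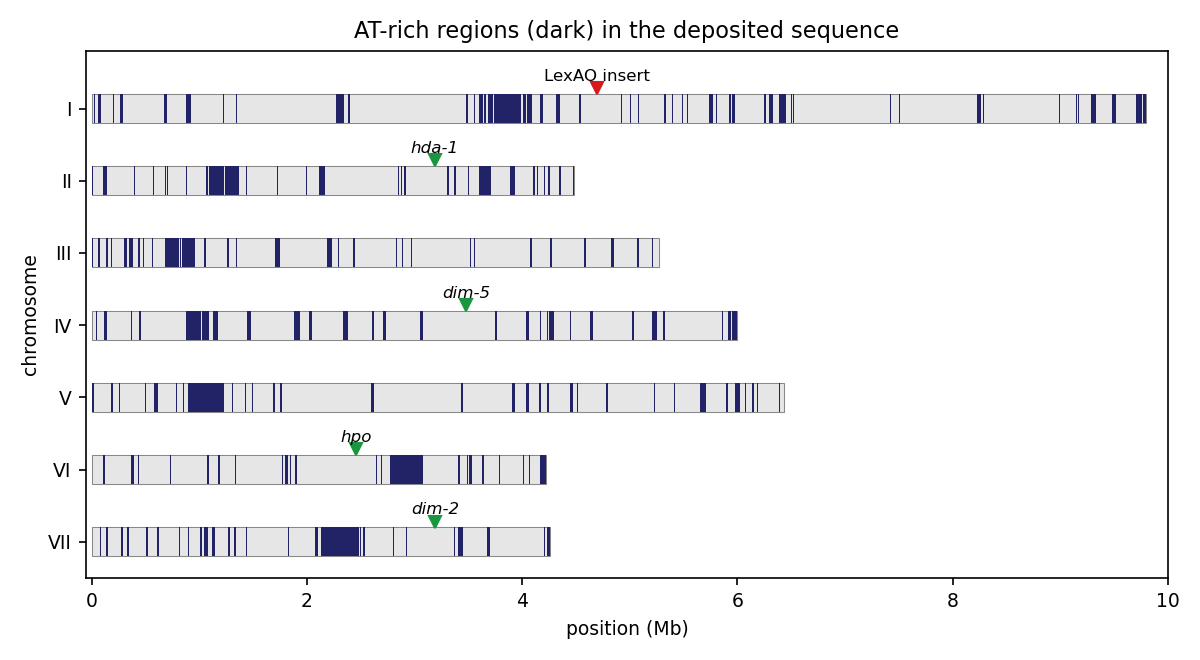
Chromosomes I to VII (y axis) to scale in Mb (x axis), with AT-rich regions dark. The red mark is the LexAO insert, 154 kb from the nearest AT-rich region, and green marks are hda-1, dim-5, hpo and dim-2.

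The nearest AT-rich DNA to the operators was 154 kb away. It was a region of 12000 bp with 28.8% GC at 4532001 to 4544000. On the other side the nearest was a region of 4000 bp with 30.4% GC at 4878001 to 4882000, 180 kb away. The longest region of chromosome I ended 726 kb before the insert. Protein-coding genes had a median distance to AT-rich DNA of 38.9 kb, and 1007 of 9729 (10.4%) lay at least as far from it as the insert. The distance fell to 138 kb with windows of 500 bp and to 120.2 kb with a GC limit of 42%.

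For the strain with tethered DIM-5, the genes of all 5 listed members of the complex in which DIM-5 acts (DCDC) were in the gene table. Protein binding was not analysed here, and none of these gene spans touched AT-rich DNA. The gene dim-5 (NCU04402, chromosome IV, 3480589 to 3482273) lay 262 kb from it. Its partners dim-7 (NCU04152), cul-4 (NCU00272), dim-8 (NCU06605) and dim-9 (NCU01656) lay 211, 267, 66.1 and 53.4 kb from it. The median of the list, 211 kb, was at percentile 99.9 of random lists of the same size, but the position depended on how AT-rich DNA was called. The median fell to 20.1 kb (percentile 49.4) with windows of 500 bp and to 26.1 kb (percentile 50.7) with a GC limit of 42%. It was 178 kb with windows called by the RIP indices and unchanged under the other 3 settings, at percentiles 97.05 to 99.95 over these 4. Their GC contents ran from 52.8% to 55.1%.

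For the strains with tethered HP1 or HDA-1, the genes of all 4 members of the deacetylase complex HCHC were found. None of these gene spans touched AT-rich DNA. The HP1 gene hpo (NCU04017, chromosome VI, 2457115 to 2459498) lay 47.1 kb from AT-rich DNA and hda-1 (NCU01525, chromosome II, 3188786 to 3192710) lay 53.3 kb from it. The other members, cdp-2 (NCU00738) and chap (NCU01796), lay 50.1 and 155 kb from it. The list's median of 51.7 kb was at percentile 60.0 of random lists, and under the alternatives it was 20.2 to 159 kb, at percentiles 30.2 to 88.6. The other deacetylase genes hda-2 (NCU02795), hda-3 (NCU00824) and hda-4 (NCU07018) lay 52.0, 43.5 and 15.1 kb away. Their median of 43.5 kb was at percentile 53.7, and under the alternatives it was 4.54 to 90.1 kb, at percentiles 7.53 to 71.1.

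The deposited sequence belongs to the series as a whole and shows nothing of the 2 deletion strains themselves. It held long stretches without a stop codon at the annotated places of the genes deleted in those strains. The longest such stretch, in any reading frame of either strand, was 1611 bp in the span of hda-1. It was 2781 bp in that of dim-2 (NCU02247, chromosome VII, 3189797 to 3195483), which lay 56.5 kb from AT-rich DNA. No start codon was required and introns were not removed, so intact coding sequences were not shown. The first 24 bases of hph, the hygromycin resistance gene that the genotypes list, had no exact match, and neither had the first 24 bases of E. coli lexA. A recoded version of either would not have been found.

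All 8 histone genes were found, with a median distance to AT-rich DNA of 12.1 kb, at percentile 2.68 of random lists. Histone genes hH4-1 (NCU01634) and hH3 (NCU01635), which neighbour each other on chromosome II, lay 0.26 and 3.35 kb from it. Both distances were to 1 isolated AT-rich window, at 2879001 to 2880000. On chromosome VII hH2B (NCU02435) lay 3.67 kb and hH2A (NCU02437) 4.19 kb from AT-rich DNA. The other 4, hH1, hH2Az, hH3v and hH4-2, lay between 20 and 50.1 kb away. Neighbouring genes are not independent, and under the alternatives the median was 12.1 to 23.0 kb, at percentiles 3.29 to 30.6. All 7 sirtuin genes were found, at 0.295 kb (nst-3, NCU03059) to 94.2 kb (nst-2, NCU00523), with a median of 35.6 kb at percentile 44.4. The region nearest to nst-3 was also 1 isolated window, at 4376001 to 4377000 on chromosome I. Under the alternatives the sirtuin median was 9.09 to 49.4 kb, at percentiles 6.14 to 51.3. With windows called by the RIP indices it was 9.09 kb, less than the 20.6 kb of histone genes. The boundary factors dmm-2 (NCU08289) and dmm-1 (NCU01554) lay 17.0 and 142 kb from AT-rich DNA, and set-7 (NCU07496), the H3K27 methyltransferase gene of PRC2, lay 23.5 kb from it. The markers near the target, his-3, lpl and ad-3A (NCU03166), lay 151, 156 and 105 kb from it, with a median at percentile 96.6, or 86.0 to 99.7 under the alternatives. These genes were listed for their shared location, so random lists of scattered genes are not a like comparison. Their percentile describes the chosen site only. None of the 34 matched list members touched AT-rich DNA. Few protein-coding genes lie there at all, with 30 of 9729 at least 50% inside it. The share of all genes that touch it was not counted, so this is not read as a trait of the lists. No gene in the table had exactly the name rid, eed, suz12, npf or ad-3B. The table does list rid-1, which was not taken to be rid and was not analysed here.

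Potential LexA sites away from the target were few in AT-rich DNA, near the number its dinucleotides predict. For some other palindromes the same model missed the AT-rich counts. The pattern CTGT, 8 bases, ACAG had 428 matches outside the target (Poisson 95% interval 388 to 471), of which 5 were in AT-rich regions (4.31 expected from dinucleotides) and 423 elsewhere (579 expected). That is 0.744 per Mb in AT-rich DNA against 12.3 per Mb elsewhere. Of the latter, 253 lay within protein-coding genes and 170 outside them. The exact consensus with alternating A and T in the spacer had 0 matches. The target itself had 0 strict matches, because each LexA box of its operator pairs departs from the palindrome. With 1 mismatch allowed there were 4 matches within the insert and 12174 outside the target. None of these sites was tested for binding.

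**Figure D4:**
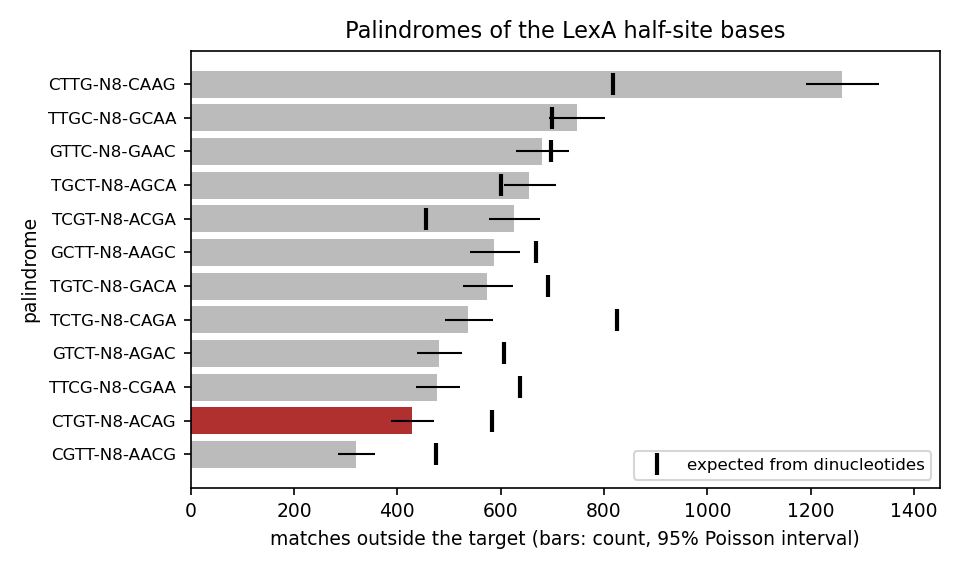
Matches outside the target (x axis) of the 12 palindromes made from the bases of the LexA repeat with 8 free bases between (y axis). Bars are counts with 95% Poisson intervals, black ticks the number expected from dinucleotides, and the LexA pattern (red) has 428 matches against 584 expected.

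Short reads differ in how well they can be placed on the target. Of the 36-mers that touch the insert, 139 of 231 (60.2%) occurred once in the sequence, and of the 50-mers 181 of 245 (73.9%). All 295 of the 100-mers did. The operator copies repeat each other within the insert, and no exact copy of the operator pair lay outside the target. A k-mer of the insert can thus be repeated without a match elsewhere in the genome. How many of the repeated k-mers had a match outside the insert was not counted. Over AT-rich regions 95.3% of 36-mers, 98.4% of 50-mers and 99.6% of 100-mers were unique, against 99.7%, 99.8% and 99.9% in other sequence.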

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

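The alternatives for the operator pattern with 2 mismatches and with a shorter half-site, those for the gene lists, for the RIP index and for genes inside AT-rich DNA, and the single-class Markov chain were added after seeing the data. The AT-rich share of 16.5% became 16.0% and 17.1% with GC limits of 38% and 42%, 15.8% with regions of at least 5000 bp only, and 17.1% when windows were called by the RIP indices. The region count of 390 became 911 with windows of 500 bp and 248 with the 5000 bp minimum, which drops short regions by construction. The distance from the insert to AT-rich DNA, 154232 bp, became 137732 bp with windows of 500 bp and 120232 bp with a GC limit of 42%; it was the same under the other 4 settings of windows and regions. The cause of these shifts with window size and GC limit was not tested. LexA matches at the target, 0 in the strict form, became 6 with 1 mismatch, 54 with 2 mismatches and 5 with CTG, 10 bases, CAG. The target here means all sequence within 5 kb of his-3. Within the insert these patterns had 4, 9 and 4 matches, so most of the 54 lay outside the operators. Outside the target, 428 matches became 0 for the exact consensus, 12174 with 1 mismatch, 144496 with 2 mismatches and 9410 with CTG, 10 bases, CAG. The DCDC list had percentiles of 49.4 to 99.95 and medians of 20.1 to 211 kb. The median TpA/ApT index of 1.38 stayed at 1.37 to 1.38 with the 5 settings that do not select windows by it. The 30 protein-coding genes inside AT-rich DNA became 49 with the RIP indices. Alternatives that need ChIP signal or an unedited genome sequence were not run. No paired analysis was possible because the result comes from no test and each strain has 1 library.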

Other observations

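The test of the shifted positions was chosen only after the result was seen; the other tests were set before their results. Of the 391 gaps in the sequence, 389 (99.5%) had flanks of less than 40% GC. Of the 14 ends of the 7 chromosomes, 9 carried at least 12 bases of the telomere repeat, and chromosome VI had it at neither end. Pseudogenes of tRNA were the annotated class with the largest share in AT-rich DNA, at 4 of 16 (25.0%, Wilson 95% interval 10.2% to 49.5%), and 4 of 77 rRNA genes (5.19%, 2.04% to 12.6%) also lay there. None of the 176 ncRNA genes did (upper limit 2.14%).

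The excess of TpA over ApT in AT-rich windows was weighed against low GC content alone. Shuffling the bases of each AT-rich window gave median indices of 0.992 to 1.01, and on 7 of 7 chromosomes the observed median of 1.37 or more lay above every shuffled value. Low GC content with bases in random order therefore does not give the observed index. Such a shuffle makes TpA and ApT equally likely at any GC content. The other windows, at 0.657 to 0.673, also lay away from the shuffled values. The test thus shows only that neighbouring bases are not independent, and cannot exclude other sources tied to base composition. A candidate explanation is C-to-T change at CpA by RIP, which also predicts a loss of CpA and TpG. The substrate index was lower in AT-rich than in other windows on 7 of 7 chromosomes. Other mutational processes with the same preference were not tested.

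LexA-type palindromes outside the target numbered 428, fewer than the 584 expected from dinucleotides, which lies above the Poisson interval of 388 to 471. With 1 chain for the whole assembly the expected number was 477, still above it. Dinucleotide composition as modelled here thus does not account for the count. In AT-rich DNA the LexA count was close to expectation, 5 against 4.31, and the shortfall lies in other sequence, with 423 against 579. The AT-rich comparison rests on 5 matches. There the same chain missed the half-sites GTTC (65 against 19.5), TTGC (20 against 5.60) and GCTT (46 against 85.9). It was close for others, such as CGTT (66 against 65.0) and TCGT (43 against 40.5). The shortfall is not particular to LexA: for 9 of the 11 other palindromes the expected number also lay outside the interval, with 6 below and 3 above expectation. The cause was not tested, and no biological explanation was tested.

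The operator insert may by itself resemble the DNA that carries H3K9me3 in this fungus. Its GC content of 38.3% was below the 40% limit set for AT-rich windows but well above their median of 27.8%. It held 32 TpA against 21 ApT, a ratio of 1.52 beside a median of 1.38 in AT-rich windows. Its substrate index is not given here. At the scale of the windows the low GC does not hold, as the 1 kb centred on the insert had 46.5% GC. Low GC over 200 bp was also not particular to the insert: steps at 4697633 to 4697832 and 4703433 to 4703632 had 37.5% and 38.5%. The array of 4 identical operator copies spans 147 bp of the 196-bp block, so the ratio mostly reflects 1 repeated sequence. The control strain carries the same insert, so a comparison with it would cover the insert's own composition. The control's ChIP signal was not analysed here.

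Features after his-3 on chromosome I lay 576 bp earlier in the deposited sequence than in the gene table. The offset was -576 bp for tRNA genes after his-3, where 39 of 44 held the motif at it and at most 3 at any distant offset, and 0 for those before. Among annotated genes between the nearest tRNA genes on both sides, 12 of 88 after his-3 ran from a start to a stop codon at the shifted position and 0 at the unshifted one; NCU10470 was the first of them. Up to his-3 this check had little power, with 2 of 63 genes at the unshifted position and 1 at the shifted one. These values are consistent with 1 edit rather than differences spread along the chromosome. If that edit is the insert, and all 338 bp from the T7 to the T3 promoter are foreign, at least 914 bp of native sequence are absent from the edited chromosome. Which bases these are was not determined here, and genes between the insert and NCU10470 were placed on this assumption.

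Inside the lower-case block, 16 bases at 4698264 to 4698279, CTGGTTTTATATACAG, were in capitals. They form the end of the first operator pair, and the other 3 pairs were in lower case throughout. No value here tells why.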
